A study of Mus musculus with 18 samples.

How the data were processed

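The samples were livers of female mice aged 6 weeks, 18 in all, in 6 groups of 3: Nrf1 CKO and its control, Nrf2 KO and its control, and Keap1 KD and its control. Per the labels, total RNA was extracted with Isogen, 500 ng was labelled with Cy3 with the Quick Amp kit and hybridized to single-colour Agilent mouse arrays. Per the file headers, the images were read with Agilent Feature Extraction, 1 array per file. Per the file headers, the intensities called processed signal were background-subtracted and detrended over space and over the multiplicative trend, raised to a surrogate where near 0, and not normalized between arrays. The deposited median intensities of each spot and of its local background are raw pixel values, per the file headers. The deposited flags for well above background, saturation and outliers, and the control type of each spot, are other output of the same software, per the file headers. The values in the authors' series table were equal to the processed signal intensities at all 810324 entries compared.

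Each array held 45018 spots, of which 1639 were controls and were left out, as were spots the software marked as non-uniform or population outliers. The log2 signals of the spots of a probe were averaged (245 of 41174 probes are printed in 10 spots), and this mean was scaled by subtracting log2 of the array's 75th percentile. A gene symbol was found for 26718 probes (64.9%), for 26690 through a RefSeq transcript and for 28 through a symbol or synonym. The 14456 others kept the accession or clone name on the array. Probes well above background on all 3 arrays of at least 1 group were tested (23554), with a probe counted above background on an array if at least 50% of its spots were. Of several probes of a gene the brightest was used, which left 17721 genes, 12874 with a symbol and 4847 without. A gene needed a value on 70% of the arrays, a rule set while writing the code, which dropped 0 genes; 51 genes had a missing value. No gene coordinates are given, since the headers name another genome build than the reference table, which was used for gene names and for the order of genes. Values of dim genes depend on the background, so where no array of a group was above it a change is given as at least so many fold. Where only some were, the log2 value is given and rests in part on values below background.

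limma (version 3.58.1, in R 4.3.3) was fitted to 6 group means over all 18 arrays (12 residual degrees of freedom, 4 with the 6 arrays of a line; 3.07 prior degrees of freedom), with moderated statistics without a trend. Adjusted p are Benjamini-Hochberg values over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The comparisons were each mutant with its own control, and the 3 differences between these effects. The median standard error of a mutant effect was 0.244 on the log2 scale. Shared calls were set against the number expected of independent lists, with Fisher's exact test across genes.

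Of 34 gene lists written from general knowledge before the values were seen (772 entries, 2 without a current symbol), the 33 with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The tests were repeated with the correlation estimated for each list and with fry, a rotation test of whether the genes of a list move one way on balance, which compares them with no other genes. The knowledge behind the antioxidant, glutathione, proteasome and lipid lists may include published work on these mice, so that these lists are not independent of them.

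The genes named were fixed by a rule: 9 genes in every comparison (Nfe2l1, Nfe2l2, Keap1, Nqo1, Gclc, Slc7a11, Mt1, Lpin1 and Ppargc1b), the 6 highest and 6 lowest called genes with a symbol and with groups that do not overlap, up to 4 called members of each list that passed or had at least 3 members called, and the 6 largest of the most common overlap of each pair of comparisons. Published work on these mice may also lie behind the choice of the 9 genes, so they are not independent of it. Genes named outside this rule are marked as such. Some genes that the rule names are not reported here.

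Alternatives fixed before the values were seen were quantile normalization, scaling to the array median, the authors' series table, no filter on background, only probes above background on all arrays, the mean of all probes of a gene, outlier spots kept, a fit of the arrays of 1 comparison, an intensity trend, array quality weights, the replicate number as a block, slide (7 slides) or scan date (4 dates) as a block, and each array of the compared lines left out in turn. Background correction by normexp could not use mean signals, which the files lack. Normexp with an offset of 50 on median signals followed by quantile normalization, and slide as a random block, were added after seeing the data. The scripts were tested on simulated data of 17721 genes. Of genes changed by 2 on the log2 scale, 95.5% (Nrf1 CKO), 81.8% (Nrf2 KO) and 97.0% (Keap1 KD) were recovered, of those changed by 1, 37.3%, 38.8% and 34.3%, and of those changed by 0.5, 2.99%, 2.99% and 0%. There were 4, 1 and 5 false calls. The list that had been shifted was called, and 0 of the others. The simulated genes varied independently of each other and without slide effects. The simulation therefore does not show how often lists whose genes move together are called falsely. Groups of 3 are too small for a test for outlying samples. Other tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.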

Results

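Gene expression was measured in livers of female mice aged 6 weeks on 18 single-colour arrays, 1 per sample, in 6 groups of 3. Each of 3 mutant lines had its own genetic control. The Nrf1 CKO mice lacked Nrf1 (gene symbol Nfe2l1) in the liver, through Cre recombinase under the albumin promoter, which is active in hepatocytes. Nrf2 KO mice lacked Nrf2 (Nfe2l2) in all tissues, and Keap1 KD mice carried a knockdown allele of Keap1 over a null allele. NRF1 and NRF2 are related transcription factors that bind antioxidant response elements, and KEAP1 targets NRF2 for degradation. The lines thus set loss of NRF1, loss of NRF2 and a genetic lowering of KEAP1 beside each other. The labels give the strain of the Nrf1 line and of the Keap1 line as mixed and that of the Nrf2 line as C57BL/6. They do not say that the 3 samples of a group were separate animals, so the p-values measure the spread between these samples, which may be technical. Between 21668 (Keap1 KD 1, 50%) and 28213 (Keap1 control 3, 65.0%) of the 43379 spots of an array were well above background. Values of samples of 1 group correlated at 0.973 to 0.991 across genes, and 17721 genes were tested, 12874 of them with a gene symbol. The number of arrays limits the precision of every value given here.

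The targeted genes came first, as a check of the labels. Nfe2l1 had a level of 3.72 ± 0.18 (SD, n = 3; log2 signal relative to the array's 75th percentile) in Nrf1 controls and −6.44 ± 0.20 in Nrf1 CKO, where its probe was not well above background on any array. The signal was at least 469-fold lower (limma, adjusted p = 5.88e-15; log2 fold change −10.17, SE 0.17, and −10.03 with slide as a block). Nfe2l2 fell from 3.32 ± 0.20 to −4.88 ± 1.5 in Nrf2 KO (−8.20, SE 0.48, limma adjusted p = 4.46e-07; −8.19 with slide and −8.68 with scan date as a block), and 1 of the 3 KO arrays, Nrf2 KO 3, remained above background. The log2 changes of Nfe2l1 and Nfe2l2 rest on mutant arrays below background, so their sizes are not measured. A second Nfe2l2 probe gave −7.30. Keap1 fell from 4.19 ± 0.80 to 1.80 ± 0.06 in Keap1 KD (−2.39, SE 0.31, limma adjusted p = 0.00124), with all 3 KD arrays above background and below every other array. The Keap1 call was lost with slide as a block (−2.03, adjusted p = 0.0774) and when only the 6 arrays of the line were fitted (−2.39, adjusted p = 0.0572). The change was −2.24 with scan date as a block, −1.41 within the 1 slide (1 array of each group) and −2.18 within the 1 scan date (1 KD array and 2 controls) that held both Keap1 groups. Whether these probes lie in the deleted part of each gene is not given in the sources used here. A probe outside it would check nothing, but the signals fell in the line named for each gene. No targeted gene passed the test in another line over all arrays: Nfe2l2 was at 0.68 (adjusted p = 0.331) in Nrf1 CKO, and Keap1 was at −0.71 (adjusted p = 0.116) there. Both passed when only the 6 Nrf1 arrays were fitted (limma adjusted p = 0.0396 and 0.0344). Nfe2l2 also passed after normexp (0.97, adjusted p = 0.00533), and Keap1 with array quality weights (−0.77, adjusted p = 0.00472). Nfe2l2 lay at 3.52 to 3.7 on the Nrf1 controls and at 4.06 to 4.45 on the CKO arrays. Keap1 lay at 3.43 to 3.79 and at 2.81 to 2.98, so that neither gene's groups overlapped.

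**Figure D1:**
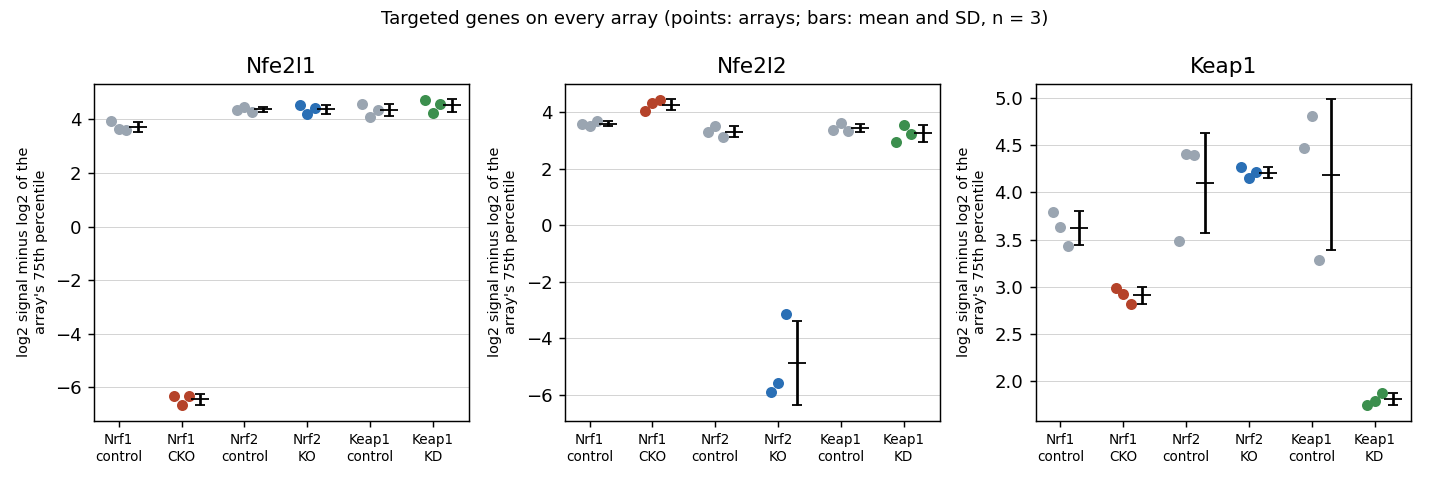
Level of Nfe2l1, Nfe2l2 and Keap1 on each of the 18 arrays (points; log2 signal minus log2 of the array's 75th percentile), with the mean and SD of each group of 3 (bars). Each gene lies lowest in the line named for it: Nfe2l1 at −6.44 in Nrf1 CKO, Nfe2l2 at −4.88 in Nrf2 KO and Keap1 at 1.80 in Keap1 KD.

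In Nrf1 CKO livers 3348 of the 17721 genes differed from control, 1416 higher and 1932 lower. By log2 fold change, the highest named genes were Gpnmb, a glycoprotein of macrophages (at least 13.3-fold higher, n = 3 in each group), the macrophage elastase Mmp12 (at least 11-fold), Ly6d (log2 fold change 5.22, SE 0.97), Ccn5 (at least 20.4-fold), Sprr1a (4.78, SE 0.89) and Hebp2 (at least 11-fold). For those given as at least so many fold, a place among the highest rests on control values below background and was not measured. After Nfe2l1 itself, the lowest were Esm1, a proteoglycan of endothelial cells (−4.67, SE 0.45), the sulfotransferase Sult3a2 (−4.07, SE 0.85), Hnf4aos, a transcript antisense to Hnf4a (−3.81, SE 0.60), Unc79 (−3.64, SE 0.71) and Fam107a (−3.17, SE 0.98). Sprr1a in controls and Fam107a in CKO were above background on 1 array. The limma adjusted p of these genes lay between 2.12e-07 (Mmp12) and 0.0359 (Fam107a). Among the genes fixed in advance, the metallothionein Mt1, which binds zinc, fell by 2.87 (adjusted p = 0.00312), Lpin1, a phosphatidate phosphatase of triglyceride synthesis, fell by 2.32 (adjusted p = 0.0125), and Ppargc1b, a coactivator of mitochondrial and lipid genes, fell by 1.48 (adjusted p = 0.0181). Slc7a11, the cystine transporter, was not well above background on any array and was not tested. Since published work on these mice may lie behind the choice of these fixed genes, they are no independent support. Changes of at least 2-fold were seen for 933 higher and 591 lower genes. Of the named genes called in the 3 lines, all but Cyp2b9, Klf1, Smad7 and Sox4 had 3 values of one group beyond the 3 of the other. Chance gives this for 10% of genes that are not selected. It was a condition for naming the highest and lowest genes, and the others were picked among called genes, so it is no check.

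Genes of the proteasome fell together in Nrf1 CKO. Of 36 measured subunits of the 26S proteasome, the complex that degrades ubiquitin-tagged proteins, 24 fell and 0 rose (1 higher and 30 lower adjusted over the list alone). Psma5 changed by −0.93 (SE 0.14), Psma6 by −0.87 (SE 0.17) and Psmc1 by −0.77 (SE 0.15), and after quantile normalization by −0.52, −0.57 and −0.47, with their calls kept. Psmd12 was at −0.93 (SE 0.18) on its brightest probe and at −0.40 and −0.79 on its 2 others. The median change was −0.61, −0.52 with slide as a block and −0.36 after quantile normalization (camera, adjusted p = 1.64e-10, and adjusted p = 0.334 with an estimated correlation). Of 43 measured antioxidant and detoxification genes regulated by NRF2, 9 rose and 1 fell (12 and 1 adjusted over the list alone). The glutathione S-transferase Gstm2 (1.36, SE 0.31), the sulfiredoxin Srxn1 (1.13, SE 0.25, and 1.73 and 1.87 on its other probes), the epoxide hydrolase Ephx1 (1.47, SE 0.31) and the carboxylesterase Ces2e (1.48, SE 0.20) were among those that rose. Nqo1, a quinone reductase (0.27, adjusted p = 0.456), and Gclc, the catalytic subunit of glutathione synthesis (0.08, adjusted p = 0.820), did not pass the test. This list's median was 0.13, or 0.17 with slide as a block (adjusted p = 0.00763, and adjusted p = 0.479 with an estimated correlation). It was 0.40 after quantile normalization and 0.03 with the array median, and the call was lost with fry (adjusted p = 0.114). Of 22 targets of ATF4 and of amino acid starvation, 5 rose and 2 fell, over the list alone as over all genes. The transcription factors Atf3 (3.43, SE 0.32) and Ddit3 (0.88, SE 0.17), the stress cytokine Gdf15 (2.04, SE 0.44) and the mitochondrial folate enzyme Mthfd2 (at least 3.04-fold) rose (list median 0.40, 0.31 with slide as a block, adjusted p = 0.00245, and adjusted p = 0.334 with an estimated correlation). Of 19 p53 targets, 12 rose and 0 fell (14 and 1 adjusted over the list alone), with Phlda3 at 2.67 (SE 0.28), the apoptosis gene Bax at 1.03 (SE 0.15), the death receptor Tnfrsf10b at least 3.46-fold and Eda2r at least 12.4-fold higher. Their median of 1.20 (0.98 with slide as a block) kept its call with an estimated correlation (adjusted p = 1.77e-10 with the preset one and adjusted p = 0.0449 with an estimated correlation).

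Cell division and matrix genes rose in Nrf1 CKO, and markers of several cell types moved with them. Of 27 proliferation genes 21 rose and 0 fell (22 and 1 adjusted over the list alone), with a median of 1.95 (1.57 with slide as a block). The mitotic kinases Aurka (2.16, SE 0.30) and Aurkb (at least 3.47-fold higher) and the replication helicase subunits Mcm6 (2.10, SE 0.34) and Mcm4 (1.66, SE 0.26) were among them. Of 22 genes of fibrosis and extracellular matrix 16 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.33 (1.19 with slide as a block). They included the metalloproteinases Mmp12, Mmp13 (at least 10.4-fold) and Mmp2 (2.34, SE 0.29) and the lectin Lgals3 (2.34, SE 0.33). Markers of stellate cells, the collagen-producing cells of the liver, rose for 9 of 17 and fell for 0 (13 and 1 adjusted over the list alone; median 0.87, 0.89 with slide as a block), such as Lum (1.75, SE 0.24), Cygb (1.37, SE 0.26) and Pdgfra (1.04, SE 0.20). Markers of Kupffer cells and macrophages rose for 6 of 21 and fell for 1 (7 and 1 adjusted over the list alone; median 0.49, 0.80 with slide as a block). Trem2 rose by 4.15 (SE 0.33), while the scavenger receptor Cd163 fell by 1.5 (SE 0.37). Of 14 markers of cholangiocytes and progenitors, Afp (1.92, SE 0.38) and Sox4 (1.60, SE 0.50) rose and 0 fell (3 and 0 adjusted over the list alone; median 0.78, 0.46 with slide as a block). Camera's adjusted p was 1.81e-15 for proliferation, 6.90e-13 for matrix, 1.04e-06 for stellate, 0.000111 for macrophage and 0.00183 for cholangiocyte genes. None of these 5 lists kept its call with an estimated correlation: adjusted p = 0.12 with an estimated correlation for proliferation, matrix and stellate genes, adjusted p = 0.435 for macrophage and adjusted p = 0.359 for cholangiocyte genes. Markers of the sinusoidal endothelium were not called as a list (18 measured, 0 higher and Lyve1 lower at −2.42; median −0.03, adjusted p = 0.863). Lymphocyte markers (18 measured, 1 higher, Cd8a), neutrophil markers (8, 0 higher and 0 lower), pancreas markers (7, 1 higher, Cela1) and erythroid markers (7, 1 higher and 2 lower) were not called by camera either. Pancreas markers (median 0.66, adjusted p = 0.0960) passed with fry (adjusted p = 0.0393). They also passed with the arrays of the line alone (adjusted p = 0.0417) and without control 3 (adjusted p = 0.0368). Lymphocyte markers (median 0.06, adjusted p = 0.218) passed with slide as a block (0.64, adjusted p = 0.00261). They also passed without control 2 (0.50, adjusted p = 0.000444) and without the filter on background (adjusted p = 0.0165). Only 4 adipocyte markers were measured, too few for the list test, and 1 of them was higher. Lyve1, Cd8a and Cela1 were named after their values were seen.

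Genes of differentiated hepatocytes and of lipid, bile acid and drug metabolism fell in the same arrays. Of 23 hepatocyte markers 13 fell and 0 rose (0 and 17 adjusted over the list alone; median −0.63, −0.51 with slide as a block), including Hpd (−1.45, SE 0.29), Tdo2 (−1.14, SE 0.25) and the transcription factor Cebpa (−0.84, SE 0.18). Of 36 genes of fatty acid oxidation 13 fell and 0 rose (0 and 16 adjusted over the list alone; median −0.50, −0.62 with slide as a block). Of 26 genes of fatty acid and triglyceride synthesis 8 fell and 2 rose (2 higher and 11 lower adjusted over the list alone; median −0.71, −0.61 with slide as a block): the desaturase Scd1 fell by 1.63 (SE 0.37) and Scd2 rose by 1.28 (SE 0.27). Of 22 genes of bile acid synthesis and transport 8 fell and 0 rose (0 and 9 adjusted over the list alone; median −0.67, −0.43 with slide as a block), such as Cyp7b1 (−2.22, SE 0.36) and the bile acid importer Slc10a1 (−1.18, SE 0.28). Of 34 drug-metabolising cytochromes P450 and targets of the nuclear receptors CAR and PXR, 10 fell and 1 rose (2 higher and 17 lower adjusted over the list alone; median −0.62, −0.54 with slide as a block), with Cyp2b10 at −2.28 (SE 0.49; −1.37 with slide as a block, where its call was lost) and the receptor CAR itself, Nr1i3, at −0.91 (SE 0.19). Of 16 genes higher in female than in male liver 6 fell and 0 rose (0 and 10 adjusted over the list alone; median −1.21, −0.99 with slide as a block), such as Cyp17a1 (−2.48, SE 0.50). Camera's adjusted p was 1.49e-06 for hepatocyte, 0.000178 for oxidation, 0.00763 for fatty acid synthesis, 0.00763 for bile acid, 0.000111 for P450 and 0.000556 for female-biased genes. With the correlation estimated, none of these 6 passed: adjusted p = 0.359 with an estimated correlation for hepatocyte, bile acid and P450 genes, 0.362 for oxidation, 0.479 for fatty acid synthesis and 0.334 for female-biased genes. After quantile normalization the calls of 4 of these lists were lost: the median was −0.10 for hepatocyte (adjusted p = 0.0914), P450 (adjusted p = 0.0556) and oxidation genes (adjusted p = 0.108), and −0.39 for bile acid genes (adjusted p = 0.108), which also lost the call with slide as a block (adjusted p = 0.215). The same 4 calls were lost after normexp (adjusted p from 0.0970 to 0.229). Without the filter on background, fatty acid synthesis (adjusted p = 0.0655) and bile acid genes (adjusted p = 0.0614) lost theirs.

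Further lists held single genes that changed, while camera did not call the list. The zinc and iron list (20 measured, 2 higher and 2 lower) held Mt1, Mt2 (−2.65, SE 0.57) and the zinc importer Slc39a4 (1.03, SE 0.21). Lipid droplet and uptake genes went both ways (22 measured, 4 higher and 3 lower): the lipase Lpl (2.37, SE 0.58) and the droplet protein Cidec (2.55, SE 0.55) rose and Plin5 fell by 1.46 (SE 0.37). Of 27 acute phase and inflammatory genes 3 rose and 6 fell, with the chemokine Ccl2 at 3.12 (SE 0.58) and Itih4 at −1.0 (SE 0.16). Glutathione S-transferases (21 measured, 3 higher and 4 lower, with Gsto1 at −1.18), NADPH enzymes (9, 1 and 3, with Pgd at 0.66), glucose metabolism (26, 0 and 4, with Fbp1 at −0.80), clock genes (16, 0 and 3) and male-biased genes (16, 3 and 2, with Cyp4a12a at 3.50) had camera adjusted p from 0.0587 (glucose metabolism) to 0.755 (male-biased genes). The median and the test had opposite signs for male-biased genes (median −0.19, test higher), and the median and the mean had opposite signs for acute phase genes (−0.28 and 0.07). Cholesterol synthesis (25, 0 and 2), heat shock genes (16, 0 and 2), glutathione synthesis (10, 1 and 1), immunoproteasome genes (18, 1 and 1) and endoplasmic reticulum chaperones (21, 0 and 0) were not called. Fry, which tests whether the genes of a list move one way on balance, did call glucose metabolism (median −0.51, adjusted p = 0.0245), clock genes (−0.82, adjusted p = 0.0356) and the zinc and iron list (−0.19, adjusted p = 0.0356). With camera, glucose metabolism passed with array quality weights (adjusted p = 0.0241), with the arrays of the line alone (adjusted p = 0.0249) and with scan date as a block (adjusted p = 0.0479). It also passed without control 3 or CKO 1 (adjusted p = 0.0385 and 0.0351). Clock genes passed with weights (adjusted p = 0.0425), lipid droplet genes without the filter (0.0477) and immunoproteasome genes without control 3 (−0.63, adjusted p = 0.0206).

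Scaling and slide bear on these counts. Before scaling, every CKO array was brighter than every Nrf1 control (75th percentile 305 to 403 against 194 to 252). More of its spots were well above background (57.5 to 60.1% against 52.3 to 54.7%). Brightness thus cannot be told apart from genotype, and changes of genes dim in the controls may depend on it. The share of higher genes among those called was 42.3%, and 55.1% after quantile normalization, and the median of all genes was −0.09, against −0.20 when each array was scaled to its median. With slide as a block, which rests on the 1 slide with 3 CKO arrays and 1 control, 41 genes were higher and 24 lower. Of the called genes, 3330 of 3348 kept their sign and their change was 0.907 times that without the block (median; quartiles 0.763 to 1.06). The median standard error rose from 0.244 to 0.335 and the residual degrees of freedom fell from 12 to 7. These genes were called with the arrays of that slide among the rest, so their sign there is no independent check. All 108 named genes that were called kept their direction with slide as a block. Their change was 0.141 times (Smad7, of the iron list, 2.18 without the block) to 1.55 times (Sag) that without it, and 8 kept the call (Atf3, Esm1, Gpnmb, Hebp2, Mmp12, Nfe2l1, Tmem35a and Trem2). Mt1 was then at −2.67, Lpin1 at −1.41 and Ppargc1b at −1.23. Normexp lowered several changes by over 1.5 times: Sult3a2 to −2.32, Unc79 to −1.76, Fam107a to −0.43, Sprr1a to 2.41, Mmp2 to 1.49, Pdgfra to 0.63 and Sox4 to 0.43, where Fam107a and Sox4 lost their calls. After quantile normalization Hpd was at −0.94, Gsto1 at −0.78, Itih4 at −0.66 and Fbp1, with its call lost, at −0.25. Without Nrf1 control 1 the counts were 602 higher and 614 lower, 604 and 577 without CKO 2, and 501 and 438 without CKO 3, and 1084 were lower without control 2. Single arrays moved the median of 4 lists: antioxidant genes to 0.03 without CKO 3 and 0.20 without control 1, ATF4 targets to 0.26 and cholangiocyte markers to 0.36 without CKO 3, and macrophage markers to 0.77 without control 2 and 0.28 without CKO 2.

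**Figure D2:**
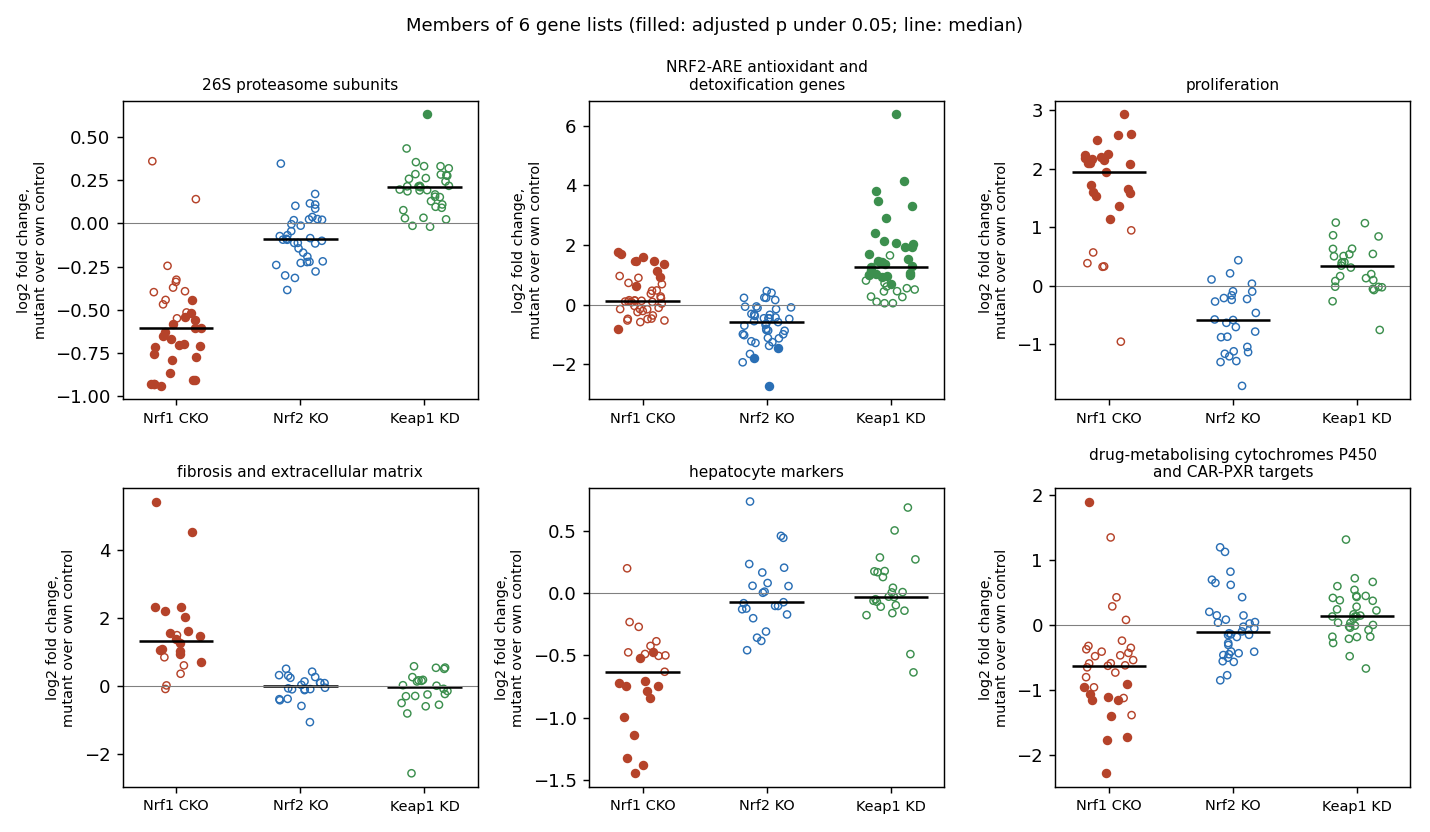
Log2 fold change of each measured member of 6 gene lists in the 3 comparisons of mutant with own control (filled points: adjusted p under 0.05; horizontal line: list median). In Nrf1 CKO the median was −0.61 for proteasome subunits and 1.95 for proliferation genes, and in Keap1 KD it was 1.27 for antioxidant and detoxification genes.

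In Nrf2 KO livers 11 genes differed from control, 1 higher and 10 lower, 9 of the latter at least 2-fold. After Nfe2l2 itself the lowest named genes were the aldehyde oxidase Aox1 (−2.73, SE 0.22, n = 3 in each group, limma adjusted p = 1.20e-05), Keg1 (−2.35, SE 0.33, adjusted p = 0.00706), the carboxylesterases Ces1b (−1.99, SE 0.16, adjusted p = 1.20e-05), Ces1f (−1.97, SE 0.23, adjusted p = 0.00133) and Ces1g (−1.79, SE 0.23, adjusted p = 0.00276). Nqo1 fell by 1.47 (SE 0.25, adjusted p = 0.0384) and the splicing factor Srsf3 by 0.86 (SE 0.13, adjusted p = 0.0182), and 2 lower genes had no symbol. The higher gene was Cox7a1, a subunit of cytochrome c oxidase (1.31, SE 0.20, adjusted p = 0.0182). Gclc (−0.46), Mt1 (0.67), Lpin1 (0.08) and Ppargc1b (0.37) did not pass the test. Of all genes tested, 1576 (8.89%) had an unadjusted limma p under 0.05. In simulated data of the same size, 38.8% of genes changed by 1 on the log2 scale were called in this comparison, and 81.8% of those changed by 2.

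Of the 43 antioxidant and detoxification genes 3 fell, Aox1, Ces1g and Nqo1, and 0 rose; adjusted over the list alone, 20 fell and 1 rose. The list's median was −0.58 (camera, adjusted p = 9.24e-19, and adjusted p = 0.0505 with an estimated correlation), −0.21 with slide and −0.32 with scan date as a block. A further 8 lists shifted with 0 members called over all genes (limma; unadjusted p under 0.05 for 0 to 8 members per direction), and none kept the call with an estimated correlation. Lower were proliferation genes (median −0.58, adjusted p = 4.99e-06, and adjusted p = 0.753 with an estimated correlation; −0.83 with slide and −0.88 with scan date as a block; 5 of 27 lower adjusted over the list alone) and male-biased liver genes (−0.55, adjusted p = 1.06e-05, and adjusted p = 0.0662 with an estimated correlation; −0.22 and −0.17; 5 of 16 lower adjusted over the list alone). Also lower were endoplasmic reticulum chaperones (−0.32, adjusted p = 0.000316, and adjusted p = 0.753 with an estimated correlation; −0.79 and −0.61; 0 of 21 adjusted over the list alone). Immunoproteasome and antigen presentation genes were higher (0.44, adjusted p = 1.32e-05, and adjusted p = 0.753 with an estimated correlation; 0.74 and 0.74; 0 of 18 adjusted over the list alone), as were genes of fatty acid synthesis (0.28, adjusted p = 0.0225, and adjusted p = 0.753 with an estimated correlation; 1.19 and 1.0; 0 of 26). Among cell type markers, those of lymphocytes (0.53, adjusted p = 0.000219, and adjusted p = 0.753 with an estimated correlation; 0.56 and 0.39; 0 of 18) and of sinusoidal endothelium (0.17, adjusted p = 0.0325, and adjusted p = 0.753 with an estimated correlation; 0.63 and 0.59; 0 of 18) were higher. Cholesterol synthesis genes were lower (−0.14, adjusted p = 0.0271, and adjusted p = 0.844 with an estimated correlation; 0 of 25 adjusted over the list alone), but their median turned to 0.53 with slide and 0.32 with scan date as a block (adjusted p = 0.0800 and 0.384). With slide and with scan date as a block, the calls of male-biased genes (adjusted p = 0.812 and 0.742) and lymphocyte markers (adjusted p = 0.0712 and 0.258) were lost too. Endothelial markers lost the call with the array median (0.11, adjusted p = 0.0570), the mean of probes (adjusted p = 0.0569) and slide as a random block (adjusted p = 0.0530). Genes of fatty acid synthesis lost it with array quality weights (adjusted p = 0.0757). Cholesterol genes lost it after quantile normalization (−0.03, adjusted p = 0.0983), after normexp (adjusted p = 0.0590) and without the filter (adjusted p = 0.202). Fry called antioxidant (adjusted p = 0.00341) and male-biased genes (adjusted p = 0.0168) and none of the other 7 lists. The 26S proteasome list had a median of −0.09 (adjusted p = 0.0930), and passed with weights (adjusted p = 0.0255) and without KO 2 (adjusted p = 0.0307). Neutrophil markers (8 measured, median 0.79, adjusted p = 0.0539) passed with the array median (adjusted p = 0.0132), without the filter (0.33, adjusted p = 0.0161) and with the arrays of the line alone (adjusted p = 0.00471). They also passed without control 3, KO 1 or KO 2 (adjusted p = 0.0483, 0.0342 and 0.0434). Clock genes (median 0.16) were at 1.17 with slide and 1.11 with scan date as a block (adjusted p = 0.0116 and 0.0138). Glutathione S-transferases (−0.12) passed camera as higher with slide (0.06, adjusted p = 0.0132) and scan date as a block (0.11, adjusted p = 0.0192). Hepatocyte markers (−0.07) passed as higher with scan date as a block (0.24, adjusted p = 0.0431). NADPH enzymes (−0.16) passed as lower with weights (adjusted p = 0.0435) and with the arrays of the line alone (adjusted p = 0.0233). Macrophage markers (0.14) passed as higher without the filter (adjusted p = 0.0190).

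No slide and no scan date held both Nrf2 groups, so there is no value within a batch, and a blocked value compares them through the Keap1 arrays that shared slides or dates with them. It rests on Keap1 control 1, without which neither block gives a value. With slide as a block 2 genes were higher and 9 lower, and with scan date 1 and 6. All 9 named genes called kept their direction in both, and Aox1 (−2.99 with slide, −3.10 with date) and Nfe2l2 kept the call. Nqo1 was then at −0.80 with slide and −0.94 with date, and Ces1f at −1.19 and −1.38. After quantile normalization Nqo1 lost its call (adjusted p = 0.0595). Nqo1 and Srsf3 kept their calls in 9 of 21 other settings each and Cox7a1 in 10 of 21. Without Nrf2 KO 1 the counts were 0 higher and 6 lower, the count of higher genes was 0 without control 3 or KO 2, and it was 2 without control 1. Arrays of the other lines bear on these calls through the shared spread: 20 genes were lower without Keap1 control 2, and 3 were higher without Nrf1 CKO 1. Genes of fatty acid synthesis lost their call without control 2, control 3 or KO 3 (adjusted p = 0.0873, 0.0621 and 0.228), and endothelial markers without control 1, control 2 or KO 1 (adjusted p = 0.124, 0.133 and 0.243). Cholesterol genes lost it without control 3 (−0.10, adjusted p = 0.263) or KO 1 (−0.07, adjusted p = 0.515) and were at −0.34 without control 1 and −0.28 without KO 2. Proliferation genes were at −0.93 without control 2 and −0.28 without control 3.

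The antioxidant and detoxification genes were higher in Keap1 KD: 28 of 43 rose and 0 fell, and 35 rose adjusted over the list alone. The carbonyl reductase Cbr3 rose by 6.39 (SE 0.46, n = 3 in each group, limma adjusted p = 6.55e-06), the glutathione peroxidase Gpx2 by 4.16 (SE 0.56), Nqo1 by 3.33 (SE 0.25, adjusted p = 6.55e-06), Aox1 by 1.94 (SE 0.22) and Gclc by 1.01 (SE 0.21, adjusted p = 0.0118). The list's median was 1.27 (camera, adjusted p = 2.77e-41, and adjusted p = 0.00184 with an estimated correlation), 1.20 with slide and 1.30 with scan date as a block, 1.20 within the slide and 1.30 within the scan date that held both groups. Of 21 glutathione S-transferases 9 rose and 0 fell (10 and 0 adjusted over the list alone), with Gsta2 at 3.81 (SE 0.56), Gsta1 at 3.49 (SE 0.51), Gstm4 at 2.40 (SE 0.27) and Gstp1 at 1.70 (SE 0.24, and 2.55 on a second probe). Their median was 0.81 (adjusted p = 1.24e-11, and adjusted p = 0.179 with an estimated correlation), 0.78 with slide and 1.02 with scan date as a block, 0.48 within the slide and 0.75 within the scan date. The transferase and antioxidant lists share members.

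In all, 168 genes were higher and 811 lower in Keap1 KD. Outside the lists, Dnase1 (at least 3.36-fold) and Tinag (at least 7.92-fold) were among the 6 highest named genes by log2 fold change. Their place there rests on control values below background and was not measured. The lowest were Tff3, a secreted trefoil peptide (−4.09, SE 0.92), the fatty acid receptor Ffar4 (−3.28, SE 0.90, above background on 1 KD array), Apoa4, an apolipoprotein (−2.77, SE 0.61), Mpp4 (at least 2.69-fold lower), Akr1c18 (−2.56, SE 0.55) and Keap1 itself, with limma adjusted p from 0.00124 (Keap1) to 0.0458 (Ffar4). The place of Mpp4 among the lowest rests on KD values below background and was not measured. Ffar4 kept its call in 8 of 20 other settings and was at −1.61 without control 2. After normexp it was at −1.33, Tff3 at −2.35 and Akr1c18 at −1.31, with their calls lost. The other lists that shifted moved by less. Of 9 NADPH and pentose phosphate enzymes, Pgd (1.14, SE 0.18) and Tkt (0.96, SE 0.21) rose, over the list alone as over all genes, and 0 fell (median 0.17, adjusted p = 0.00324, and adjusted p = 0.375 with an estimated correlation; 0.36 with slide and 0.29 with scan date as a block, 0.37 within the slide and 0.34 within the date). Of 36 proteasome subunits 1 rose, Psmb5 (0.63, SE 0.17), and 0 rose adjusted over the list alone (median 0.21, adjusted p = 6.45e-05, and adjusted p = 0.721 with an estimated correlation; 0.21 and 0.18 with the blocks, 0.09 and 0.07 within the slide and the date). The proteasome call was lost after quantile normalization (0.10, adjusted p = 0.0773). Of 25 cholesterol synthesis genes 1 rose, Mvk (0.78, SE 0.21), over the list alone as well (median 0.25, adjusted p = 0.00427, and adjusted p = 0.847 with an estimated correlation; 0.33 and 0.54 with the blocks, 0.27 and 0.63 within batches), a call also lost after quantile normalization (0.12, adjusted p = 0.0845). Of 22 bile acid genes 4 rose and 0 fell (5 and 0 adjusted over the list alone): the efflux pumps Abcc4 (2.92, SE 0.44) and Abcc3 (1.53, SE 0.25), Cyp7b1 (1.93, SE 0.36) and Hsd3b7 (0.86, SE 0.20). That list's median was 0.03 (adjusted p = 0.00801, and adjusted p = 0.516 with an estimated correlation; 0.10 and 0.12 with the blocks, 0.02 and 0.10 within batches). It lost its call with slide as a block (adjusted p = 0.0928), and after quantile normalization (adjusted p = 0.143), where the median was −0.00. Proliferation genes (27 measured, median 0.34, adjusted p = 0.0203, and adjusted p = 0.942 with an estimated correlation; 0.36 and 0.38 with the blocks, 0.22 and 0.62 within batches) and acute phase genes (27 measured, median −0.40, adjusted p = 0.0401, and adjusted p = 0.721 with an estimated correlation; −0.47 and −0.45 with the blocks, −0.29 and −0.47 within batches) had 0 members called by limma, over all genes or over the list alone. At an unadjusted p under 0.05, 3 proliferation genes were higher and 2 acute phase genes lower. The acute phase call was lost with slide as a block (adjusted p = 0.109), slide as a random block (adjusted p = 0.0870) and the mean of probes (adjusted p = 0.0521). The proliferation call was lost with the strict filter (adjusted p = 0.0807) and after normexp (0.17, adjusted p = 0.0619). Cyp7b1, Gstp1 and Ugt2b1 (1.52, SE 0.28) rose among 16 male-biased genes, and that list was not called (adjusted p = 0.346). No list of cell type markers was called. Macrophage markers had 1 member higher (Trem2, 1.51, of 21 measured), endothelial markers 1 higher (Lyve1, 1.09, of 18), stellate markers 1 lower (Lum, −0.87, of 17) and pancreas markers 1 lower (Cela1, −1.27, of 7), all named after their values were seen. Mt1 (0.72), Lpin1 (−0.13) and Ppargc1b (−0.08) did not pass the test.

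**Figure D3:**
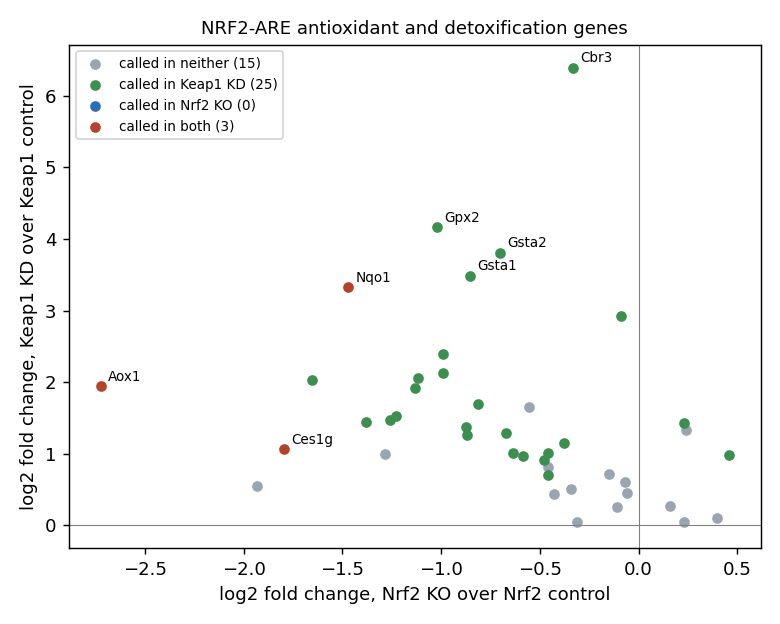
Log2 fold change of the 43 antioxidant and detoxification genes in Nrf2 KO (horizontal axis) and in Keap1 KD (vertical axis), each mutant over its own control, with 1 point per gene coloured by the comparisons that called it. Of these genes, 3 were called in both comparisons, 25 in Keap1 KD alone and 15 in neither.

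Most genes lower in Keap1 KD carried no gene symbol. Of the 811, 716 had none, of which 543 were named only by cDNA clone, against 26 of the 168 higher genes. Among genes without a symbol 14.8% were lower, and among those with one 0.738% (Fisher's exact test across genes, which are not independent replicates, odds ratio 23.3, p = 2.75e-307). These 716 genes were dim and moved together. Their median level was −2.01 to −2.47 on the 3 Keap1 controls and −3.45 to −4.23 on the 3 KD arrays, −2.34 to −2.80 on the 6 arrays of the Nrf1 line and −3.53 to −4.33 on the 6 of the Nrf2 line.

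**Figure D4:**
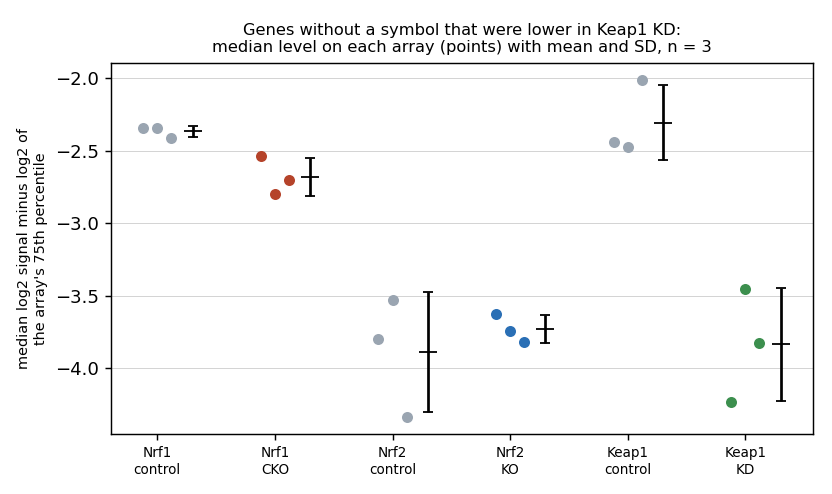
Median level (log2 signal minus log2 of the array's 75th percentile) of the 716 genes without a symbol that were lower in Keap1 KD, on each array (points), with the mean and SD of each group of 3 (bars). The Keap1 KD arrays lie between −3.45 and −4.23, below the Keap1 controls, and those of the Nrf2 line between −3.53 and −4.33.

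The split of higher and lower genes in Keap1 KD depended on the scaling. The share of higher genes among those called was 17.2%, and 27.4% after quantile normalization, 27.6% after normexp with quantile normalization and 48.8% with each array scaled to its median, which moved the median change of all genes from 0.00 to 0.29. With slide as a block 9 genes were higher and 46 lower, and with scan date 55 and 200. The change of the 979 genes called was 1.17 times that over all arrays within the slide and 1.05 times within the scan date that held both groups (medians). These values rest on 1 KD array each, which was also among the arrays that called the genes, and are no independent check. All 34 named genes called kept their direction with either block. With slide as a block the change was 0.688 (Tmem35a) to 1.34 times (Psmb5) that without it, and Aox1, Cbr3, Gstm4 and Nqo1 kept the call. When only the 6 arrays of the line were fitted, 18 genes were higher and 34 lower. In Nrf1 CKO the same kind of fit gave 1024 and 1358. Residual SDs were 0.343 to 0.446 on the Keap1 arrays and 0.244 to 0.377 on those of the other lines. The spread shared by the 3 lines thus lay below that of the Keap1 line, which favours calls in it. Without Keap1 control 3 the counts were 94 higher and 256 lower, and 373 were lower without KD 1 and 464 without KD 3.

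The smaller list shifts in Keap1 KD depended on the test, the scaling and single arrays. Fry called antioxidant genes, glutathione S-transferases (adjusted p = 0.00352) and NADPH enzymes (adjusted p = 0.0299) and none of the other 5 lists (adjusted p from 0.0984 for bile acid to 0.767 for proliferation genes). After normexp cholesterol (adjusted p = 0.0511) and bile acid genes (−0.03, adjusted p = 0.0642) lost their calls. With the array median, where the median of all genes was 0.29, the medians were 0.46 for NADPH enzymes, 0.50 for proteasome, 0.54 for cholesterol, 0.32 for bile acid, 0.64 for proliferation and −0.11 for acute phase genes, with their calls kept. With array quality weights they were 0.51 for glutathione S-transferases, 0.12 for proteasome and 0.65 for proliferation genes. Drug-metabolising P450 genes (median 0.13, adjusted p = 0.108) passed with slide (0.26, adjusted p = 0.0295) and with scan date as a block (0.26, adjusted p = 0.0217). They also passed without control 1 or KD 3 (adjusted p = 0.0129 and 0.0207). Glutathione synthesis genes (0.09, adjusted p = 0.108) passed with a trend (adjusted p = 0.0369), without the filter (0.23, adjusted p = 0.0485) and without control 2 or KD 2 (0.31 and 0.22, adjusted p = 0.0326 and 0.0262). Heat shock genes passed without KD 2 (0.24, adjusted p = 0.00976) and endoplasmic reticulum chaperones without KD 1 (−0.39, adjusted p = 0.0127). Proliferation genes lost their call without control 1 (0.09, adjusted p = 0.422), control 2 (0.32, adjusted p = 0.108), KD 2 (0.29, adjusted p = 0.0979) or KD 3 (0.12, adjusted p = 0.438), and were at 0.60 without control 3 and 0.70 without KD 1. Cholesterol genes lost it without control 2 (0.10, adjusted p = 0.209) or KD 3 (0.25, adjusted p = 0.129) and were at 0.43 without KD 2. NADPH enzymes lost it without KD 1 (0.05, adjusted p = 0.0783) and were at 0.27 to 0.35 without control 1, control 2, KD 2 or KD 3. Acute phase genes lost it without control 1, control 2, KD 2 or KD 3 (−0.42, −0.24, −0.28 and −0.33, adjusted p = 0.139, 0.187, 0.106 and 0.242). Bile acid genes lost it without control 2 (0.05, adjusted p = 0.0724), and their median was −0.03 without KD 1 and 0.11 to 0.17 without control 1, control 3, KD 2 or KD 3. Glutathione S-transferases were at 0.47 without control 3 and proteasome subunits at 0.12 without KD 1, with their calls kept.

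The effects of the lines were then compared with each other in the same fit, and the genes given here were picked from the named ones after their values were seen. The effect of Nrf1 CKO exceeded that of Nrf2 KO for 533 genes and was below it for 455. Aox1 (difference 3.19, SE 0.31, limma adjusted p = 0.000115) was above, and Mt1 (−3.54, SE 0.73, adjusted p = 0.0149), Esm1 (−5.06, SE 0.63, adjusted p = 0.00101) and Psma5 (−0.81, SE 0.20, adjusted p = 0.0319) below. Against Keap1 KD, the effect of Nrf1 CKO was above for 630 genes and below for 596. Mt1 differed by −3.58 (SE 0.73, adjusted p = 0.0157), Psma5 by −1.14 (SE 0.20, adjusted p = 0.00913), Nqo1 by −3.05 (SE 0.35, adjusted p = 0.000408) and Cbr3 by −4.78 (SE 0.65, adjusted p = 0.00160). The effect of Nrf2 KO was above that of Keap1 KD for 370 genes, 298 of them without a symbol, and below it for 178, 151 of them with a symbol. Nqo1 (−4.80, SE 0.35, adjusted p = 4.99e-06), Aox1 (−4.67, SE 0.31, adjusted p = 3.07e-06), Cbr3 (−6.73, SE 0.65, adjusted p = 7.47e-05), Gpx2 (−5.18, SE 0.80, adjusted p = 0.00452) and Gclc (−1.47, SE 0.30, adjusted p = 0.0188) were below.

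These counts of differing genes moved by over 1.5 times without most of the single arrays. For Nrf1 CKO against Nrf2 KO they were, higher and lower, 223 and 125 without Nrf1 control 1, 352 and 240 without Nrf1 control 2, 949 and 1182 without CKO 1, 224 and 110 without CKO 2 and 198 and 96 without CKO 3. Among the arrays of the Nrf2 line they were 354 and 296 without control 1, 260 and 160 without control 3, 241 and 147 without KO 1, 344 and 212 without KO 2 and 254 and 165 without KO 3. For Nrf1 CKO against Keap1 KD the higher genes were 155 without Nrf1 control 1, 1057 without CKO 1, 226 without CKO 2, 164 without CKO 3, 357 without Keap1 control 2, 419 without Keap1 control 3 and 312 without KD 1. The lower genes of that comparison were 108 without Nrf1 control 1, 293 without Nrf1 control 2, 1255 without CKO 1, 133 without CKO 2, 107 without CKO 3, 1124 without Keap1 control 1, 240 without Keap1 control 2, 282 without KD 1 and 367 without KD 2. For Nrf2 KO against Keap1 KD the higher genes were 236 and 103 without Nrf2 control 1 and 3, 94, 194 and 151 without KO 1, KO 2 and KO 3, 129 without Keap1 control 3 and 185 without KD 1, and the lower genes were 103 without Nrf2 control 3 and 81, 117 and 92 without KO 1, KO 2 and KO 3. With slide as a block they were 5 and 3, 6 and 5, and 7 and 20, and with scan date as a block 112 and 89, 176 and 153, and 26 and 54.

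Genes called in more than 1 line were counted last. Of the 10 genes lower in Nrf2 KO, 5 were higher in Keap1 KD, against 0.0948 expected of independent lists (Fisher's exact test across genes, which are not independent replicates, p = 1.75e-08): Aox1, Ces1g (1.06 in Keap1 KD, SE 0.23), Nqo1, Srsf3 (0.61, SE 0.13) and 1 gene without a symbol. With slide or with scan date as a block the count was 1, without Nrf2 control 2 or KO 1 it was 2, without Nrf2 KO 3 or Keap1 KD 2 it was 3, and without Keap1 control 2 it was 9. Between Nrf1 CKO and Keap1 KD, 35 genes were higher in both, against 13.4 expected (Fisher's exact test across genes, p = 1.21e-07), and 44 were lower in both, against 88.4 expected (p = 3.49e-08). The latter included the membrane protein Tmem35a (at least 4.18-fold lower in Nrf1 CKO and at least 1.80-fold in Keap1 KD), the amino acid transporter Slc3a1 (−1.82 and −1.28) and the cyclin Ccnl2 (−0.83 and −0.95), as well as Sag, Cyp2d13 (−1.31 and −1.01) and Gin1 (−0.98 and −0.92). Higher in Nrf1 CKO and lower in Keap1 KD were 15, against 64.8 expected (Fisher's exact test, p = 1.43e-14), and 14 went the other way, against 18.3 (p = 0.321). The shortfall of genes lower in both did not hold in every setting. There were 29 against 28.5 expected after quantile normalization (Fisher's exact test, p = 0.922) and 30 against 36.5 with the array median (p = 0.290). Without CKO 1 there were 118 against 114 (Fisher's exact test, p = 0.679), and without KD 1 41 against 44.0 (p = 0.685). After normexp there were more than expected (55 against 31.3, Fisher's exact test, p = 4.12e-05), as with array quality weights (62 against 48.6, p = 0.0256), so its direction depends on the processing. With own arrays 0 genes were higher in both against 1.04 expected, too few to judge the excess. For genes higher in Nrf1 CKO and lower in Keap1 KD, own arrays (1 against 1.96) and slide as a block (1 against 0.106) gave too few to judge the shortfall. Without CKO 3 there were 12 such genes against 20.0 (Fisher's exact test, p = 0.0638). Genes lower in Nrf1 CKO and higher in Keap1 KD exceeded their expected count without CKO 2 (11 against 4.56, Fisher's exact test, p = 0.00612) or CKO 3 (8 against 3.63, p = 0.0298). They fell short of it with weights (12 against 21.1, Fisher's exact test, p = 0.0189) and without KD 1 (11 against 19.0, p = 0.0493). Nrf1 CKO and Nrf2 KO shared 1 gene lower in both, Ces1f (−0.87 in Nrf1 CKO, SE 0.23), and 1 gene higher in Nrf1 CKO and lower in Nrf2 KO, Srsf3 (0.64 in Nrf1 CKO, SE 0.13), against 1.09 and 0.799 expected (Fisher's exact test, p = 1 and 0.565). In Nrf1 CKO, Ces1f was at −0.41 after quantile normalization, and after normexp Srsf3 was at 0.25 there, −0.43 in Nrf2 KO and 0.34 in Keap1 KD, all with the call lost. With slide as a block 1 gene was higher in both Nrf1 CKO and Keap1 KD and 1 was lower in both, and with scan date as a block 10 and 12.

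Single arrays moved the counts shared by Nrf1 CKO and Keap1 KD. Genes higher in both were 18 without Nrf1 control 1, 11 without CKO 2, 10 without CKO 3, 21 without KD 2 and 16 without KD 3. Genes lower in both were 8 without Nrf1 control 1, 11 without Nrf1 control 2, 118 without CKO 1, 6 without CKO 2, 7 without CKO 3 and 23 without Keap1 control 3. Genes higher in Nrf1 CKO and lower in Keap1 KD were 9 without Nrf1 control 1 or CKO 2, 27 without CKO 1 and 8 without Keap1 control 3 or KD 1, and those that went the other way were 7 without Nrf1 control 1, 8 without CKO 3 and 28 without Keap1 control 1.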

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

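No result met the rules for outlying samples, which need groups of 4 or more. The tests of this part were fixed before their results, except those of slide without the shared slide, of variation within single groups and of a lower share of hepatocytes, which were chosen after related results had been seen. That a scan date value resting on 1 array decides nothing was also set after its result. Regrouping the 6 arrays of a line gives 10 splits into 3 and 3, too few to tell chance from effect: 1 of the 10, the real one, reached the real count in each line. The real counts were 3348 called genes for Nrf1 CKO, 11 for Nrf2 KO and 979 for Keap1 KD, and the highest counts of another split were 48, 1 and 399. For the differences between the effects, 100 splits were drawn. The real count was reached by 1 of them for Nrf1 CKO minus Nrf2 KO (988, highest other 749), by 1 for Nrf2 KO minus Keap1 KD (548, highest other 323) and by 4 for Nrf1 CKO minus Keap1 KD (1226, highest other 2288). In the 3 other splits of the last, the Nrf1 arrays kept their real groups while the Keap1 arrays were turned or mixed. The 5 genes lower in Nrf2 KO and higher in Keap1 KD were reached by 1 of 100 splits, the real one, with 1 as the highest other count. No other split of the Nrf2 arrays called more than 1 gene, so 5 could be reached only with those arrays in their real groups. These draws therefore do not tell whether the changes in the 2 lines go opposite ways beyond chance.

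The many genes called in Nrf1 CKO were weighed against a difference between slides and against a lower share of hepatocytes. Had slide caused them, Nrf1 control 3, the 1 control on the slide of the CKO arrays, would have been near CKO. In 3096 genes called without it, the change against control 3 was 0.723 times that against the other controls (median; lower quartile 0.473), and 91.1% kept their sign. This rests on 1 array, so slide stays open. A lower share of hepatocytes would raise the markers of all other liver cells alike. Stellate markers had a mean of 0.71 (17 genes, SD 0.60) and endothelial markers of −0.09 (18 genes, SD 0.68), a difference of 0.80 (permutation test across genes, which are not independent replicates, p = 0.000340). Endothelial markers as a set thus did not rise, as a lower share alone would have them do. Genes of a list can move together, and both lists were chosen after related results had been seen, so a lower share is not excluded. A change within stellate cells, or in their number, was not told apart from loss of Nrf1 acting in hepatocytes.

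The genes called in Nrf2 KO were weighed against scan date, since no date held both groups. With scan date as a block the median ratio of the changes was 0.966 (lower quartile 0.766), but this rests on 1 array, Keap1 control 1, and excludes nothing. Of the 11 genes, 63.6% differed between Keap1 controls of later and earlier dates in the direction of the Nrf2 KO effect. Scan date stays open. Loss of Nrf2 stays a hypothesis for these calls, and beside Nfe2l2 itself Aox1 kept its call with slide or scan date as a block.

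The 716 genes without a symbol that were lower in Keap1 KD were weighed against 1 control array, slide, and RNA or DNA that varies between samples. Leaving out each Keap1 control gave median ratios of 0.884 (without control 3), 1.05 and 1.06. The 716 genes were called with all Keap1 controls among the arrays, so these ratios are no independent check. In 83 such genes called without the slide that held both groups, the change on that slide was 0.913 times that on the others (median, with a lower quartile of 0.692). With slide as a block the 716 changed by 1.11 times (lower quartile 0.992). The value on the slide rests on 1 array of each group, and the 716 were called with both among the arrays, so slide stays open. On the 12 arrays of the other lines the median of these genes varied more than that of 100% of 1000 random sets of genes (SD 0.192 against 0.0595). Of the summed squares 83.3% came from the Nrf2 controls (0.07, 0.38 and −0.43 from their mean). The Nrf1 CKO arrays varied more than those of 100% of the random sets (SD 0.156 against 0.0660). For the Nrf2 KO arrays this share was 90.6% (SD 0.0911 against 0.0744). The Nrf1 controls (−0.03, 0.04 and −0.02) varied more than those of only 2.3% of the random sets. Variation from sample to sample was thus seen in some groups and not in all, and it stays open. Controls of different lines lay as far apart as the Keap1 groups (−2.34 to −2.41 in the Nrf1 line, −3.53 to −4.33 in the Nrf2 line). Such a difference thus stays open for the whole shift, beside the lowering of Keap1. Every Keap1 KD array also had fewer spots well above background (21668 to 24074) than every Keap1 control (24426 to 28213). The 716 genes were dim. With each array scaled to its median, 372 genes with or without a symbol were lower in Keap1 KD, against 811. A difference between arrays in signal over background, or in its scaling, was not tested as a cause and stays open too.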

How the results depend on the processing

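Alternatives were fixed beforehand, except normexp on median signals with quantile normalization and slide as a random block, which were chosen after seeing the data. Normexp on mean signals was not run, since the files hold none. The authors' series table gave identical results, and keeping outlier spots or slide as a random block (consensus correlation −0.0160) moved no count of genes by over 1.5 times. Nfe2l1 and Nfe2l2 kept their direction and calls in every setting that tested them, and in the strict filter they were not tested. Keap1 was −2.39 (adjusted p = 0.0572) with only its own 6 arrays and −2.03 (adjusted p = 0.0774) with slide as a block. Of the lists called, the cholesterol list in Nrf2 KO reversed, to 0.53 with slide and 0.32 with scan date as a block, and the median of the bile acid list in Keap1 KD turned from 0.03 to −0.00 with quantile normalization, −0.03 with normexp and −0.03 without KD 1, while its test kept its direction; the causes were not tested. Signal over background limits the dim genes: 32282 genes were tested without the filter and 13759 with the strict one. Blocks and fits of fewer arrays have fewer degrees of freedom, and more or fewer genes tested change the adjustment. Fits of the arrays of 1 line also drop the spread shared with the other lines, which lay below that of the Keap1 line. For the other settings the cause was not tested.

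Counts are given as higher and lower, and ranges with 1 array left out cover the arrays of the compared lines. Leaving out arrays of the other lines gave 1 to 3 higher and 9 to 20 lower genes in Nrf2 KO, and moved no count of Nrf1 CKO or Keap1 KD by over 1.5 times. In Nrf1 CKO (1416 and 1932) they became 939 and 1178 without the filter, 3514 and 5190 with array quality weights, and 41 and 24 with slide as a block, and 1254 were lower after quantile normalization; with 1 array left out they were 501 to 1709 and 438 to 2451. In Nrf2 KO the 1 higher gene became 2 with quantile normalization, mean of probes, slide as a block and normexp, 3 with a trend, 24 with weights, and 0 without the filter or with its own arrays (0 to 2 with 1 array left out). Its 10 lower genes became 21 with the array median, 6 with its own arrays, 18 with a trend, 92 with weights and 6 with scan date as a block (6 to 10 with 1 array left out). In Keap1 KD the 168 higher genes became 355 with the array median, 91 without the filter, 18 with its own arrays, 72 with weights, 9 with slide and 55 with scan date as a block (94 to 197 with 1 array left out). Its 811 lower genes became 403 with quantile normalization, 372 with the array median, 373 with normexp, 524 without the filter, 312 with the strict one, 34 with its own arrays, 166 with weights, 46 with slide and 200 with scan date as a block (256 to 933 with 1 array left out).

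For Nrf1 CKO minus Nrf2 KO (533 and 455) the counts were 345 and 227 with the array median, 199 and 115 without the filter, 899 and 943 with own arrays, 2299 and 3365 with weights, 5 and 3 with slide and 112 and 89 with scan date as a block (198 to 949 and 96 to 1182 with 1 array left out). For Nrf1 CKO minus Keap1 KD (630 and 596) they were 386 and 2194 with the array median, 206 and 147 without the filter, 175 and 93 with own arrays, 1186 and 1593 with weights, 6 and 5 with slide and 176 and 153 with scan date as a block, and 306 were lower with quantile normalization and 395 with normexp (155 to 1057 and 107 to 1255 with 1 array left out). For Nrf2 KO minus Keap1 KD (370 and 178) they were 115 and 298 with the array median, 86 and 71 without the filter, 125 and 97 with own arrays, 7 and 20 with slide and 26 and 54 with scan date as a block, and 137 were higher with quantile normalization, 103 with normexp and 160 with the strict filter (94 to 494 and 81 to 166 with 1 array left out). The lists called in Nrf1 CKO were 15, 18 with fry and 1 with an estimated correlation (15 to 18 with 1 array left out). In Nrf2 KO they were 9, 0 with an estimated correlation and 2 with fry (7 to 11). In Keap1 KD they were 8, 5 with quantile normalization or normexp, 1 with an estimated correlation and 3 with fry (5 to 8).

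The 5 genes lower in Nrf2 KO and higher in Keap1 KD became 11 with the array median, 2 without the filter, 8 with the strict filter, 1 with own arrays, 10 with a trend, 16 with weights, 1 with slide or scan date as a block and 11 at an adjusted p under 0.1 (2 to 9 with 1 array left out). The 1 gene that went the opposite way became 2 with weights and 0 with the array median, no filter, own arrays, slide or scan date as a block (0 to 2), and those lower in both, 0, became 2 with slide or scan date as a block and 1 at 0.1 (0 to 1). For Nrf1 CKO and Nrf2 KO, 0 genes higher in both became 4 with weights (0 to 1), and 0 lower in Nrf1 CKO and higher in Nrf2 KO became 10 with weights and 1 with quantile normalization, the array median, a trend, normexp or 0.1 (0 to 1). The 1 gene higher in Nrf1 CKO and lower in Nrf2 KO became 2 with quantile normalization, the strict filter, a trend or 0.1, 3 with normexp, 23 with weights and 0 with the array median, no filter, slide, scan date or a 2-fold threshold (0 to 1). The 1 lower in both became 3 with the array median, 2 with the strict filter, a trend or 0.1, 17 with weights and 0 with quantile normalization, own arrays, slide, scan date, normexp or a 2-fold threshold (0 to 2). For Nrf1 CKO and Keap1 KD, the 35 higher in both became 10 without the filter, 0 with own arrays, 1 with slide, 10 with scan date, 65 at 0.1 and 19 at 2-fold (10 to 49). The 44 lower in both (88.4 expected) became 29 with quantile normalization (28.5 expected), 10 without the filter (19.1), 0 with own arrays (2.61), 1 with slide (0.0623), 12 with scan date (20.0), 160 at 0.1 and 19 at 2-fold (6 to 118). The 15 higher in Nrf1 CKO alone and lower in Keap1 KD became 5 with quantile normalization or no filter, 4 with the array median or the strict filter, 1 with own arrays or slide, 8 with weights, 3 with scan date, 6 with normexp and 45 at 0.1 (8 to 27). The 14 that went the other way became 30 with the array median, 6 without the filter, 1 with own arrays, 0 with slide, 5 with scan date, 36 at 0.1 and 8 at 2-fold (7 to 28).

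With the replicate number from the titles as a block (replicate block), the counts were 0 and 5 in Nrf2 KO, 109 and 527 in Keap1 KD, 271 lower for Nrf1 CKO minus Nrf2 KO, 378 lower for Nrf1 CKO minus Keap1 KD, and 113 and 86 for Nrf2 KO minus Keap1 KD. Shared genes were then 2 lower in Nrf2 KO and higher in Keap1 KD, 0 the opposite way, 0 for the 2 single genes shared by Nrf1 CKO and Nrf2 KO, and 26 lower in both Nrf1 CKO and Keap1 KD. Residuals of a mutant and a control of the same number correlated at 0.127, 0.121 and −0.0171 in the Nrf1 line, −0.0775, −0.0512 and 0.0525 in the Nrf2 line and 0.101, −0.359 and 0.147 in the Keap1 line, so that the numbers do not pair the samples, and calls lost with this block say nothing about the effects.

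Of the named genes that were called, calls were lost for 137 with slide and 27 with scan date as a block, 53 with own arrays, 27 with normexp, 24 without the filter, 22 with quantile normalization, 17 with the replicate block, 15 with weights, 14 with the array median, 2 with the mean of probes and 2 with the strict filter. Over all fits with 1 array left out, calls were lost 179 times. None of the called genes changed direction.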

Other observations

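The tests of this part were fixed before their results were seen, except the rule that too few expected calls decide nothing, which was not among what was fixed. A segment of chromosome carried along with the targeted allele could change its neighbours' expression, so the 200 nearest genes with a symbol were compared with all others. For Nfe2l1, 36 of 200 neighbours were called in Nrf1 CKO (18%) against 20.9% of the others (Fisher's exact test, one-sided, across genes, p = 0.860), so no excess was seen. With 41.7 expected, a segment that changed only a few neighbours would not show in this test, and it stays open. For Nfe2l2, 0 of 200 were called in Nrf2 KO (Fisher's exact test, p = 1), but with 0.0639% of the others called only 0.128 were expected, so this test decides nothing. For Keap1, 6 of 200 were called in Keap1 KD (3%) against 1.76% (Fisher's exact test, p = 0.146), which leaves it open. The 6 were Acad8, Ccdc159, Col5a3, Dcun1d5, Tbcel and Thyn1, named after their values were seen.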
